A study of Caenorhabditis elegans with 6 samples.

How the data were processed

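RNA of whole worms was hybridised to 6 Affymetrix C. elegans arrays, 3 of wild type and 3 of hlh-30(tm1978). Per the labels' protocols, worms were grown at the standard laboratory temperature on plates, eggs were isolated by bleaching, embryos and synchronised L1 and L2 larvae were collected, and RNA of the 3 stages was combined within each of 3 biological replicates per genotype. Labelled RNA was made by in vitro transcription with biotin, also per the labels' protocols. The authors deposited log2 expression values, 1 per probe set and array. Per the submitters' processing notes, GCRMA (a method for Affymetrix arrays whose background correction uses probe sequence) and limma were used, and their versions and settings are not given in the sources used here. The lowest value, 2.04, is shared by all arrays and acts as a floor, and other values are also exactly identical between some arrays. Scanner intensities were not analysed here, so no detection call or scan date could be used.

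Samples were grouped by the genotype in their labels. The replicate numbers come from the sample titles, and the labels do not say that a number marks a shared culture or day. Probe sets were named through the platform annotation supplied with the values: 20766 carried 1 gene, 887 several and 895 none, and 20701 of the first kind were matched by Entrez gene number to RefSeq, with 0 symbols changed. Genes were named only from probe sets with 1 gene. The 77 control probe sets were left out. A probe set was tested if its log2 value was at least 4 on at least 3 of the 6 arrays, which left 12060 of them. A gene was represented by its own probe set with the highest mean over all arrays, which gave 9113 genes of the 17118 on the array.

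The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 contrast, mutant minus wild type, no covariate), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Where the mutant values lay under the log2 minimum of 4, a fold is given as a lower bound, with each value under that minimum set to it. All adjusted p-values come from limma or its set tests. With 3 arrays against 3, an exact permutation test of a single gene cannot give a p under 0.1. The median log2 change over genes was −0.010, and the scaling alternatives moved it to at most 0.051.

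Before the data were examined, 34 gene lists were written from general knowledge of HLH-30, of the pooled stages and of other tissues a whole worm holds, and 33 had at least 5 tested genes. They were tested with limma's camera with a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the lists, and also with the correlation estimated from the residuals, with ranks in place of values, and with fry. No list call held with the estimated correlation, where the lowest adjusted p was 0.499. That mode also limits the test to the few residual degrees of freedom of the arrays, which the preset mode does not. For autophagy the estimate was 0.0157, near the preset 0.01, yet the unadjusted camera p went from 1.65e-05 to 0.0158. For autophagy, the call lost in that mode therefore cannot be put down to correlation between genes alone. Over the called lists that estimate was the lowest. The highest were 0.756 for histones, 0.631 for glycolysis and gluconeogenesis and 0.58 for body wall muscle. The preset of 0.01 lies far under these, so the preset camera p-values of such lists may be much too small. Members of a list were also adjusted over the list alone. The rule for named genes, fixed at the same time, takes hlh-30, up to 12 genes with the largest rise and 12 with the largest fall among called genes whose arrays do not overlap, and up to 4 members of each list with the smallest adjusted p. Families of genes with a shared symbol prefix and at least 10 tested members were tested with camera as an exploration.

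The fit was tested on simulated data built on these 12060 probe sets for 3 arrays against 3, with 200 probe sets changed in each of 20 runs. It recovered 62.1% of the 2-fold and 89.0% of the 4-fold changes, and 4.79% of its calls were false. The simulated noise was normal and independent between probe sets, with no outlying array, floor or identical values. These rates therefore need not hold for the deposited values, which have all of these. The alternatives fixed before the data were examined were no filter and a stricter filter, quantile normalization and median centring, values floored at 4, a trended and robust variance, array quality weights, only probe sets with plain names, the mean of all probe sets of a gene, the replicate number as a block, each array left out in turn, other thresholds of p and fold, and the other set tests. Chosen after seeing the data were the fit without wild type 3 and mutant 3 and the fit with the mean of the early embryo list per array as a covariate. To ask whether brightness alone gives a list's deviation on 1 array, 10000 random lists of the same size were drawn, matched on mean expression in 20 bins. Their genes were drawn without regard to correlation within a list. The shares therefore speak to brightness only and do not measure chance for correlated genes. No genome build is named in the sources used here, so no coordinates are given.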

Results

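Transcript levels were measured on 6 Affymetrix arrays in whole Caenorhabditis elegans, a nematode worm, with 3 arrays of the wild-type strain N2 and 3 of a strain carrying the tm1978 allele of hlh-30. HLH-30 is a basic helix-loop-helix transcription factor, the worm counterpart of mammalian TFEB, which is known to activate lysosomal and autophagy genes. Each replicate was a separate biological sample in which RNA of embryos, L1 larvae and L2 larvae had been combined, so a value is an average over these stages and over all tissues. Each array held 22625 probe sets, 77 of them controls, with deposited log2 values from a floor of 2.04 to a maximum of 16.95. Between 31.7% and 32.4% of the probe sets of an array lay at that floor. A total of 12060 probe sets, representing 9113 genes, passed the filter on dim signals and were tested, and the number of arrays limits the precision of every comparison.

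The comparison asked which transcripts differ when hlh-30 is mutated. The hlh-30 transcript itself (Entrez gene 177157) was lower on each of the 3 mutant arrays than on every wild-type array at all 3 of its probe sets. At the brightest, 174862_at, the wild-type arrays read 12.05, 12.07 and 12.34 and the mutant arrays 10.52, 10.65 and 9.66 on the log2 scale. The means were 12.16 ± 0.16 (SD, n = 3) and 10.28 ± 0.54 (SD, n = 3), a log2 difference of −1.88 (SE 0.29) with an adjusted p of 0.128 in limma over all probe sets tested. The other probe sets, 190299_at and 194161_s_at, differed by −2.15 (SE 0.32) and −2.28 (SE 0.51), with limma adjusted p of 0.121 and 0.26. Adjusted over these 3 probe sets alone, the limma p-values were 0.0021, 0.0021 and 0.0068. Whether the probe sets lie in the part of the gene altered by tm1978 is not given in the sources used here, so they check the labels only through the separation of the arrays.

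Of the genes tested, 12 fell and 1 rose in the mutant at an adjusted p under 0.05. Among them was tts-1 (Entrez gene 180490), a long noncoding RNA known as abundant in long-lived insulin-receptor mutants. No wild-type array read under 11.32, and the mutant arrays averaged 4.17 ± 0.88 (SD, n = 3), a fall of at least 130-fold (fitted log2 change −7.23, SE 0.46; limma adjusted p 0.0321). The chemoreceptor-family gene srw-85 (Entrez gene 182903) averaged 8.66 ± 0.63 (SD, n = 3) in wild type and stood at the floor of 2.04 on all 3 mutant arrays, at least 25.2-fold lower (limma adjusted p 0.0210). Whether the mutant strain was outcrossed is not given in the sources used here, so the comparison does not separate hlh-30 from other differences between the strains. The only gene that rose, Y49G5A.1, went from 6.43 ± 0.10 (SD, n = 3) to 8.14 ± 0.22 (SD, n = 3), a log2 change of 1.71 (SE 0.13; limma adjusted p 0.0398). epg-9, which encodes the worm counterpart of the autophagy-initiation protein ATG101, changed by −1.0 (SE 0.074).

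Among the other genes that fell, tnt-2, a muscle troponin T, changed by −1.01 (SE 0.070). psd-1, a phosphatidylserine decarboxylase that makes phosphatidylethanolamine, changed by −1.15 (SE 0.088). best-24, of the bestrophin chloride-channel family, changed by −1.04 (SE 0.061). The remaining 6 carry only sequence names. F31F7.1 changed by −3.12 (SE 0.21) and F59C6.16 by −3.01 (SE 0.14), the latter at least 7.17-fold because its mutant values lay under the log2 minimum of 4. ZC395.5 and F07A11.4 each changed by −2.54, with SE of 0.18 and 0.14. F26A3.4 changed by −1.5 (SE 0.12) and C50F4.8 by −0.81 (SE 0.059). Adjusted p in limma ran from 0.0210 to 0.0474 over these 13 genes, and each was read by 1 probe set. In each of them the 3 mutant arrays lay wholly on one side of the 3 wild-type arrays.

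**Figure D1:**
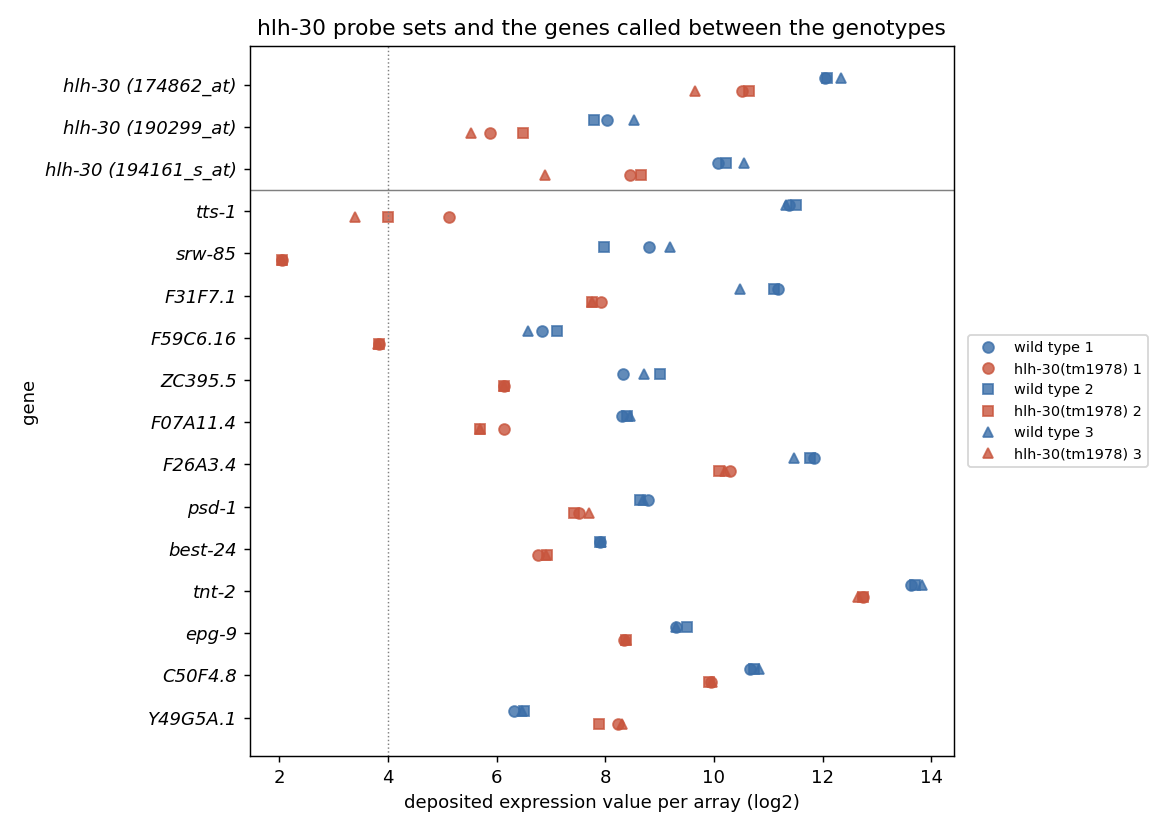
Deposited log2 value (horizontal axis) of each of the 6 arrays for the 3 hlh-30 probe sets and for the 13 genes called between the genotypes, with blue symbols for wild type, red symbols for hlh-30(tm1978), symbol shape for the replicate number, and a dotted line at the log2 minimum of 4. The mutant symbols of srw-85 sit together at the floor of 2.04, and those of tts-1 spread from 3.39 to 5.13.

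At the level of probe sets, 14 were called lower and 2 higher. These included 1 annotated with no gene, 1 annotated with 2 genes, and 191884_s_at of the nuclear receptor gene nhr-10, which changed by −0.65 (limma adjusted p 0.0321). The brighter probe set of nhr-10, which stands for the gene, read −0.54 with a limma adjusted p of 0.161. At an unadjusted p under 0.05 there were 783 genes, 151 higher and 632 lower, where chance alone gives 455.6. The arrays of the genotypes did not overlap for 1242 genes, or 13.6%, where chance gives 10%. Leaving out any 1 array left 0 to 2 genes called, and without the filter on dim signals 1 gene was called, not among the 13. Without wild type 3 and mutant 3, which stood apart from their groups, 204 genes were called, 7 of them among the 13, but only 57 of the 204 (27.9%) had the same sign between those left-out arrays.

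Of the 33 gene lists tested, 17 were called with all arrays and 12 without wild type 3 and mutant 3, with 6 in both. Called in both, and also with each array left out in turn, were 3: autophagy, cuticle collagens and ribosomal proteins. Autophagy genes were lower in the mutant as a group. Of the 35 tested, 27 had a fitted change below 0, with a median of −0.14 on the log2 scale and a camera adjusted p of 9.08e-05 (adjusted p = 0.499 with an estimated correlation). The rotation test fry, which asks whether the genes of a list move one way on balance, gave an adjusted p of 0.0406. Only epg-9 fell over all genes tested. Its values were identical on 2 wild-type arrays, and without wild type 3 and mutant 3 it read −1.04 (limma adjusted p 0.0569). Adjusted over the list alone, 5 genes fell. Among these were atg-18, a WIPI-family lipid-binding protein, at −1.14 (SE 0.12), atg-13, a subunit of the initiating kinase complex, at −0.81 (SE 0.11), and lgg-2, an LC3-family protein, at −0.58 (SE 0.077). Without wild type 3 and mutant 3 the median of the list was −0.25 and its camera adjusted p 0.00201.

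Lysosomal genes were shifted the same way. Of 57 hydrolases and lysosomal membrane proteins, 45 had a fitted change below 0, with a median of −0.16 and a camera adjusted p of 9.08e-05 (adjusted p = 0.499 with an estimated correlation). None was called over all genes, and 2 fell adjusted over the list alone. These were cpr-4, a cathepsin B-like protease, at −1.12 (SE 0.17) and scav-3, a scavenger-receptor-family membrane protein, at −0.69 (SE 0.089). Without wild type 3 and mutant 3 the lysosomal median was −0.14 and the list was no longer called (camera adjusted p 0.0661). Subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, had a median of −0.13 over 18 genes and were not called (camera adjusted p 0.066), although they were without wild type 2 (median −0.17, 0.0162) and without mutant 2 (−0.17, 0.0207), as well as with no filter (−0.13, 0.0176). Their median was −0.082 without wild type 3 (0.376), −0.052 without mutant 3 (0.277) and −0.036 without both (0.842). Of the lysosomal acid lipases only 3 of 8 passed the filter, too few for a list test, and lipl-5, lipl-6 and lipl-7 read −0.22, 0.22 and 0.087 with none called.

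Genes of fatty acid oxidation and fat mobilisation were lower, with 34 of 40 fitted below 0, a median of −0.24 and a camera adjusted p of 0.000115 (adjusted p = 0.499 with an estimated correlation). Adjusted over the list alone, 2 fell: atgl-1, the adipose triglyceride lipase, at −1.06 (SE 0.15) and dhs-18, a short-chain dehydrogenase, at −1.12 (SE 0.16). None was called over all genes, and without wild type 3 and mutant 3 the median was −0.14 and the list was not called (camera adjusted p 0.075). Without wild type 3 alone the median was −0.14 and without mutant 3 alone −0.19, with the call kept in each case (0.000156 and 0.00798). Genes of fatty acid synthesis and desaturation had 21 of 28 members below 0, a median of −0.14 and a camera adjusted p of 0.00948 (adjusted p = 0.61 with an estimated correlation). The call was lost without mutant 3 (median −0.083, camera adjusted p 0.309), without both arrays numbered 3 (median −0.063, 0.62), with array quality weights (−0.093, 0.183) and with the early embryo covariate (−0.099, 0.154). In that list the desaturase gene fat-4 fell by 0.35 (SE 0.044) adjusted over the list alone.

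Body wall muscle markers and genes of glycolysis and gluconeogenesis were also lower, and these lists moved with the 2 arrays numbered 3. Of 39 muscle markers, 34 were below 0, with a median of −0.24 and a camera adjusted p of 7.59e-07 (adjusted p = 0.61 with an estimated correlation). One of them, tnt-2, fell over all genes, and 7 fell adjusted over the list alone, among them the troponin I gene unc-27 at −0.66 (SE 0.063), the calponin-like gene clik-1 at −0.66 (SE 0.089) and the myosin light chain gene mlc-3 at −0.65 (SE 0.12). The muscle list lay 0.30 above the other wild types on wild type 3, its deviation on mutant 3 from the other mutants was −0.31, and without both arrays its median was −0.025 and it was not called (camera adjusted p 0.842). With either array left out alone the median was −0.12 and the call was kept (0.0035 and 0.0329), and the 7 genes kept 65% to 93.6% of their changes without both. Array quality weights ended the call (median −0.052, 0.183). Of 25 genes of glycolysis and gluconeogenesis, 24 were below 0, with a median of −0.30 and a camera adjusted p of 9.28e-08 (adjusted p = 0.61 with an estimated correlation). None was called over all genes, and 3 fell adjusted over the list alone, none of them a step of sugar breakdown. They were tps-2, which makes trehalose phosphate, at −0.94 (SE 0.096), and the gluconeogenic genes fbp-1 at −0.40 (SE 0.071) and pyc-1 at −0.89 (SE 0.17). On mutant 3 this list deviated by −0.33 from the other mutants, on wild type 3 by 0.10 from the other wild types, and without both arrays its median was −0.10 and it was not called (camera adjusted p 0.124), while the 3 genes kept 81.4% to 92.0% of their changes. Without mutant 3 alone the median was −0.14 and without wild type 3 alone −0.25, with the call kept (0.000457 and 0.000156), as it was with array quality weights (−0.10, 0.00983).

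Histone genes and early embryo transcripts were higher in the mutant when all arrays were used, and both lists turned below 0 without the arrays numbered 3. Of 23 histone genes, many of which are near-identical copies that one probe set cannot tell apart, 21 were above 0, with a median of 0.25 and a camera adjusted p of 0.000163 (adjusted p = 0.638 with an estimated correlation). Of 28 early embryo and maternal transcripts, 20 were above 0, with a median of 0.15 and a camera adjusted p of 0.0395 (adjusted p = 0.682 with an estimated correlation). No member of either list was called. On mutant 3 the histones lay 0.68 and the embryo transcripts 0.94 above the other mutants, and on wild type 3 they deviated by −0.34 and −0.25. Without both arrays the medians were −0.037 and −0.22 and neither list was called (camera adjusted p 0.653 and 0.129). Without mutant 3 alone they were 0.034 and −0.15 (0.271 and 0.498), and with array quality weights 0.022 and −0.16 (0.53 and 0.39). The embryo call was also lost without wild type 3 (median 0.033, 0.225) and, at medians near that of all arrays or above it, without wild type 2 (0.14, 0.0623), after quantile normalization (0.17, 0.085) and after median centring (0.22, 0.0928).

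Shifts upward were seen in 5 further lists, none of which had a called member, over all genes or adjusted over the list alone. Ribosomal protein genes were above 0 in 66 of 70 cases, with a median of 0.071 and a camera adjusted p of 7.6e-11 (adjusted p = 0.499 with an estimated correlation), and the size depended on the scaling, with a median of 0.027 after quantile normalization, where the list was not called (0.243), and 0.13 after median centring. Cuticle collagens were above 0 in 76 of 99 cases (median 0.12, camera adjusted p 7.59e-07; adjusted p = 0.499 with an estimated correlation). Their median was 0.076 without mutant 1, where the call was kept (0.000801), and the collagen genes with the smallest p went both ways, col-174 at 0.28 and col-39 at −0.55. Moulting-cycle genes had a median of 0.11 over 43 genes (camera adjusted p 0.0117; adjusted p = 0.67 with an estimated correlation), and the call was lost without wild type 3 (median 0.045, 0.19) or mutant 1 (0.049, 0.183). It was lost without mutant 2 at a median of 0.12 (0.0899), and kept without mutant 3 (0.20, 0.000123) and without both arrays numbered 3 (0.11, 0.00201). Sperm and vitellogenin transcripts, which belong to adults, had a median of 0.18 over 11 genes (camera adjusted p 0.00475; adjusted p = 0.499 with an estimated correlation), and were not called without mutant 1 (median 0.091, 0.0691) or at a mean log2 value of at least 6 (0.11, 0.0897). Without wild type 2 the median was 0.093 and the call was kept (0.026). Glutathione S-transferases were called upward at a camera adjusted p of 0.0302 (adjusted p = 0.67 with an estimated correlation), with a median of 0.036 and a mean of −0.0070 over 36 genes. These transferases lay 0.46 above the other wild types on wild type 3, and their median was 0.27 without that array (camera adjusted p 5.32e-07), 0.15 without mutant 3 (0.00798) and 0.33 without both (2.77e-06). It was −0.018 without wild type 1 (0.503), 0.027 without wild type 2 (0.20) and 0.0090 without mutant 2 (0.231), and the call was also lost after quantile normalization (0.064, 0.12) and median centring (0.097, 0.155).

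The list of insulin signalling and DAF-16 targets was lower, with 22 of 27 below 0, a median of −0.20 and a camera adjusted p of 0.00302 (adjusted p = 0.61 with an estimated correlation). Its members did not move one way: adjusted over the list alone, tts-1 and dod-3 (−1.67, SE 0.35) fell, while sod-3, a mitochondrial superoxide dismutase, rose by 0.93 (SE 0.18). Without both arrays numbered 3 the list was not called (median −0.17, camera adjusted p 0.124), and without mutant 3 alone it was called at a median of −0.12 (0.00927). Nuclear hormone receptors had 83 of 111 below 0, a median of −0.075 and a camera adjusted p of 0.00432 (adjusted p = 0.61 with an estimated correlation). Adjusted over the list alone, nhr-17 at −1.46 (SE 0.13) fell, and so did nhr-90, by at least 1.36-fold, as its mutant values lay under the log2 minimum of 4. The receptors were not called without wild type 3 (median −0.042, camera adjusted p 0.15), without mutant 3 (−0.046, 0.309) or without both (−0.0031, 0.569), nor with array quality weights (−0.0059, 0.975) or no filter (0.0801). Intestine markers (median −0.16 over 26 genes) and heat shock proteins (median −0.19 over 23 genes) both had a camera adjusted p of 0.0148 (adjusted p = 0.61 with an estimated correlation for each), with no member called. The intestine call was lost without wild type 3 (median −0.12, camera adjusted p 0.159), mutant 3 (−0.082, 0.271) or both (−0.11, 0.842), and at medians near −0.18 without mutant 1 (0.0691) and with array quality weights (0.183). The heat shock call was lost without mutant 3 (median −0.12, 0.0739), and also without wild type 3 (−0.24, 0.116) and without both (−0.19, 0.28), where the median stayed as large. Array quality weights also ended it (−0.12, 0.19). Without wild type 1 the median was −0.10 and the call was kept (0.018).

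Infection-response genes were not called as a list (camera adjusted p 0.168 over 22 genes, with a median of −0.042 and a mean of 0.11). They were called upward without mutant 3 (median 0.047, camera adjusted p 0.00798), without both arrays numbered 3 (0.041, 0.0148), with array quality weights (0.0061, 0.0273) and with the early embryo covariate (0.0041, 0.0262). Adjusted over the list alone 2 of them rose, irg-5 by 1.21 (SE 0.14) and irg-4 by 0.70 (SE 0.093). Genes of larval arrest and starvation had a median of −0.20 over 17 genes and a camera adjusted p of 0.0969, and were called lower without mutant 2 (median −0.27, 0.0454), with no filter (−0.091, 0.0233), with the replicate block (0.045) and after quantile normalization (−0.18, 0.0323) or median centring (−0.14, 0.033). The median was −0.088 without wild type 1 (0.346), −0.10 without mutant 3 (0.0768) and −0.26 without both arrays numbered 3 (0.118). In that list aak-2, a catalytic subunit of AMP-activated kinase, at −0.72 (SE 0.14), acs-2, an acyl-CoA synthetase, at −1.49 (SE 0.33), and aqp-1, an aquaporin, at −0.46 (SE 0.11) fell adjusted over the list alone. F-box protein genes had a camera adjusted p of 0.0627 with a median of 0.073 over 86 genes, and lay 0.72 above the other mutants on mutant 3. Their median turned to −0.10 without mutant 3 (camera adjusted p 0.336) and to −0.25 without both arrays numbered 3, where they were called lower (0.0131). They were called higher without wild type 1, wild type 2, mutant 1 or mutant 2 (medians 0.14 to 0.23), with the mean of all probe sets (0.043) or with the replicate block (0.045), and had a median of −0.0074 without wild type 3 (0.774). The members that fell adjusted over the list alone were fbxa-24 at −2.21 (SE 0.25) and fbxa-156 at −0.75 (SE 0.092). Among basic helix-loop-helix factors, hlh-30 was the single member to fall adjusted over the list alone, and the list of 24 was not called (median 0.070, camera adjusted p 0.781; −0.23 and 0.083 without both arrays numbered 3).

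The remaining lists were not called with all arrays and held no gene that passed adjusted over the list alone. Cytochrome P450s and UDP-glucuronosyltransferases, both enzymes of detoxification, had medians of −0.20 and −0.21 (camera adjusted p 0.145 and 0.233). On wild type 3 the P450s lay 1.04 above the other wild types. They were called lower without wild type 1 (median −0.40, camera adjusted p 0.00555), without mutant 2 (−0.35, 0.036), after median centring (−0.14, 0.0426) and with no filter (−0.0033, 0.0464), with a median of 0 without both arrays numbered 3 (0.083). The glucuronosyltransferases were called lower without mutant 2 (−0.20, 0.0428) and with no filter (−0.067, 0.0233), with a median of 0.023 without both (0.138). Oxidative stress defence genes had a median of −0.019 (camera adjusted p 0.272) and TOR signalling genes −0.083 (0.302). Antimicrobial lysozymes, saposins and peptides had a median of 0 (0.757), as did C-type lectins (0.802). Pharynx markers had a median of −0.13 (0.302), neuron markers −0.044 (0.806) and germline genes −0.020 (0.802). Without both arrays numbered 3, pharynx markers turned to 0.16 and were called higher (0.00682), as were neuron markers at 0.043 (0.0282; 0.0407 with array quality weights), whereas without wild type 2 pharynx markers were called lower at −0.27 (0.0224). Proteasome genes had a median of −0.022 (0.781) and the mitochondrial respiratory chain 0.0036 (0.802). Without both arrays numbered 3 both were called lower, at −0.17 (0.00027) and −0.12 (0.00065), as they were with array quality weights (0.00612 and 0.00118). The proteasome was called lower also without wild type 3 alone, at −0.14 (0.00544), the values in brackets being camera adjusted p throughout.

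The calls of several lists also depended on other settings, given here as medians with camera adjusted p. The early embryo covariate ended those of intestine markers (−0.096, 0.15), heat shock proteins (−0.13, 0.107), nuclear hormone receptors (−0.060, 0.154) and early embryo transcripts (−0.051, 0.57). The last loss was largely fixed in advance, as the covariate is the mean of that same list. A minimum mean log2 value of 6 ended those of early embryo transcripts (0.14, 0.0962) and glutathione S-transferases (0.00022, 0.0779), and the mean of all probe sets that of early embryo transcripts (0.12, 0.0537). With plain probe sets only, the calls of fatty acid synthesis (−0.099, 0.0543), glutathione S-transferases (0.077, 0.0521), heat shock proteins (−0.17, 0.0831) and insulin signalling (−0.15, 0.152) were lost. So were those of intestine markers (−0.16, 0.144), the moulting cycle (0.083, 0.149) and early embryo transcripts (0.069, 0.183). Autophagy stayed called while its median ran from −0.076 after median centring to −0.25 without both arrays numbered 3, and so did lysosomal genes at −0.095 after median centring.

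**Figure D2:**
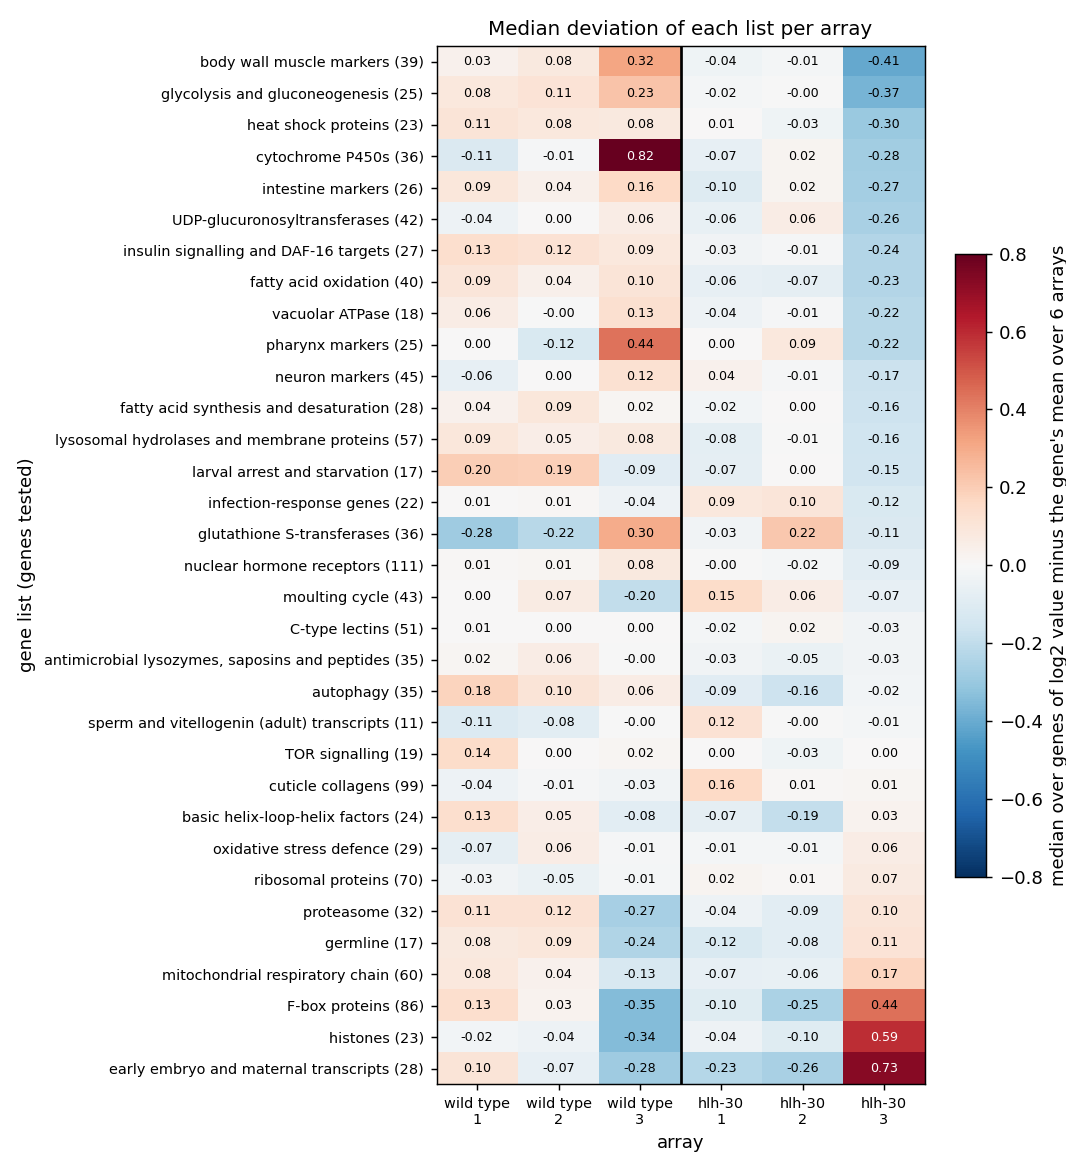
Median deviation of each of the 33 tested gene lists (rows, with the number of genes tested in brackets) on each of the 6 arrays (columns), as the log2 value minus the gene's mean over all 6 arrays, with red above and blue below 0. Early embryo transcripts reach 0.73 on mutant 3, where muscle markers read −0.41, and cytochrome P450s reach 0.82 on wild type 3.

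The arrays numbered 3 stood apart within both genotypes. The SD over tested probe sets of the difference between 2 arrays was 0.22 for wild type 1 and 2 and 0.21 for mutant 1 and 2. It was 0.53 between wild type 1 and 3, 0.67 between mutant 1 and 3, and 0.85 between wild type 3 and mutant 3. The first principal component held 57.6% of the variance and placed wild type 3 (36.6) and mutant 3 (−54.5) at opposite ends. Between them, wild type 1 and 2 lay at −7.21 and −4.86 and mutant 1 and 2 at 12.7 and 17.1. The genotypes thus differed along it in these arrays too, in the opposite order to the arrays numbered 3. The fit without both arrays numbered 3 is therefore not free of this component. The second component held 21.2% and separated the genotypes, with wild types from −18.4 to −14.2 and mutants from 6.23 to 22.2. The third component held 14.9% and placed both arrays numbered 3 on one side, wild type 3 at −23.4 and mutant 3 at −15.7. The other arrays lay from 4.07 to 14.4 along it, and the cause of this shared deviation was not tested.

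**Figure D3:**
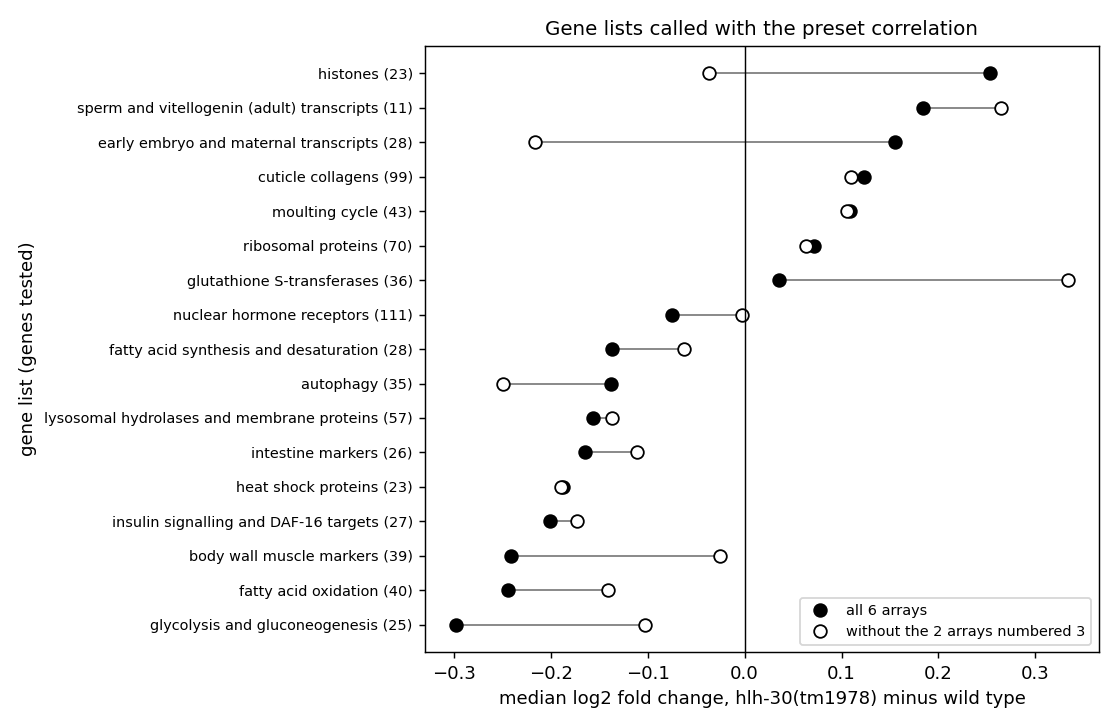
Median log2 fold change, mutant minus wild type (horizontal axis), of the 17 gene lists called with the preset correlation, with filled circles for all 6 arrays and open circles without wild type 3 and mutant 3. Autophagy moves from −0.14 to −0.25, whereas body wall muscle moves from −0.24 to −0.025 and early embryo transcripts from 0.15 to −0.22.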

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

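The tests on the arrays numbered 3 and on the lists without them were chosen only after those results were seen, apart from that on the lysosomal list. That test was set before its own result was seen, but the fit it uses was chosen after seeing the data. The count of identical values by brighter and dimmer group was also chosen after results were seen. The tests of identical values as a whole and of other splits were planned.

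Probe set 180592_s_at, annotated with 2 genes and so outside the comparison of genes, carries a far higher signal in the mutant than in the wild type. It read 4.33 on all 3 wild-type arrays and averaged 11.16 ± 0.36 (SD, n = 3) on the mutant arrays, a log2 difference of 6.82 with a limma adjusted p of 0.0037, the smallest of all probe sets tested. The wild-type value is identical on all 3 arrays, so it may be a background level, in which case the size rests on it. Which of its genes is read and whether the strain was outcrossed are not given in the sources used here, and no explanation was tested.

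The arrays of wild type 3 and mutant 3 stand apart from their groups in opposite directions along the first component, so a swap of their labels was tested on hlh-30. On a scale from the other mutants (0) to the other wild types (1), mutant 3 lay between −1.04 and −0.376 and wild type 3 between 1.19 and 1.36 over the hlh-30 probe sets, which argues against a swap. Many other genes lay on the opposite side. Of the 204 called without both arrays, 141 lay nearer the wild types on mutant 3 and 152 nearer the mutants on wild type 3. A swap could give such counts, but so could the first component, along which the other arrays of the genotypes differ in the opposite order. The counts therefore cannot tell these apart. That test and a circular one on the 13 called genes were both run before the judgement was rested on hlh-30. A brightness-dependent difference left by the normalization is argued against for the early embryo and muscle lists, since at most a share of 0.0004 of brightness-matched random lists deviated as far on mutant 3. This difference cannot be told apart from other causes for pharynx markers there, at 0.0975. On wild type 3, which that test left out, pharynx markers deviated by 0.41 and the share was 0.0001. A different share of embryo RNA in the pools may explain the pattern and stays open: early embryo transcripts lay 0.94 above the other mutants on mutant 3 (21 of 28 genes) and deviated by −0.25 on wild type 3 (22 of 28 below), with muscle and pharynx markers going the other way, and 3 of the 28 genes are also in another list.

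Beyond the share of embryo RNA, no biological explanation was tested for these arrays. The level of single embryo transcripts on them was uneven. The maternal gene pos-1 read 12.69 on mutant 3 against 9.13 on the other mutants, and 10.21 on wild type 3 against 11.33 on the other wild types. Of the brighter genes of that list, tbb-2, a tubulin, deviated by −0.15 on mutant 3, skr-1 by 0.29 and skn-1 by −0.72. Moulting-cycle genes deviated downward on both arrays, by −0.18 on mutant 3 and −0.24 on wild type 3. So did genes of larval arrest and starvation, by −0.27 on mutant 3 and −0.38 on wild type 3.

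Most called genes were lower, and many called probe sets hold exactly identical values on several arrays of a group. This was so for 9 of the 16 called probe sets (56.2%) and 31.6% of all tested ones (Fisher's exact test, one-sided, p = 0.0361). In 6 of the 9 the identical values lie only in the dimmer group, where a change that brings the signal down to a plateau makes them by itself, so this test does not separate cause from effect. In the brighter group 3 of the 16 called and 20.1% of all tested probe sets hold identical values. These 3 are the probe sets of epg-9 and best-24, and 175278_at, which is annotated with no gene. That account of a fall to a plateau does not apply to them. Whether values held at a plateau by the authors' background correction gave too small a spread and so a call cannot be told apart from a change of the transcripts. The genes tts-1, F26A3.4, psd-1, tnt-2, C50F4.8 and Y49G5A.1 hold no identical values within a group. A biological effect of the genotype stays open for all of them, as the design names it.

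For the gene lists called with the preset correlation, the share carried by the arrays numbered 3 was tested. Of the muscle, glycolysis, histone and early embryo lists, all 4 lost over 50% of their median or changed sign without both arrays, so these shifts of the lists may come from those arrays. The 7 muscle and 3 glycolysis genes that fell adjusted over their list alone, and so were picked for their change, stayed lower without both arrays. Only tnt-2 (−0.92) and tps-2 (−0.86) passed there over all genes, each at a limma adjusted p of 0.042, and the others ran from 0.055 (unc-27, −0.62) to 0.101 (unc-54, −0.39), with unc-87 at −0.50 (0.0694). The autophagy median without both arrays was −0.25 and the lysosomal median −0.14, which argues against those arrays as the origin of these shifts, although the lysosomal call was lost. As median deviations per array, autophagy read 0.057 on wild type 3 and −0.024 on mutant 3. The other wild types read 0.18 and 0.10 and the other mutants −0.092 and −0.16, so the arrays numbered 3 differed less. Lysosomal genes read −0.0052 on mutant 2. The fit without both arrays is also not free of the first component. An effect of the hlh-30 genotype stays open for the autophagy and lysosomal lists.

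Of the 10 splits of the 6 arrays into 3 and 3, the real one called 16 probe sets and the highest other 0, and 1 split, the real one, called as many. With 10 splits a share under 0.05 cannot be reached.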

How the results depend on the processing

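The fits without both arrays numbered 3 and with the early embryo covariate were chosen after seeing the data. Direction held for all 13 called genes in each setting run; their calls did not. Against 13 genes called, the count was 1 without the filter, 589 with array quality weights, 28 with the mean of all probe sets, 204 without both arrays numbered 3, 1 with the embryo covariate, 0 at an adjusted p under 0.01 and 6 with a minimum fold of 1.2 in the model. It was 0 to 2 with any 1 array left out. The array quality weights were 0.266 for wild type 3 and 0.119 for mutant 3. They were 1.75 and 1.78 for wild type 1 and 2, and 6.76 and 1.5 for mutant 1 and 2. That setting therefore comes near to leaving out both arrays numbered 3, and its mutant mean rests mostly on mutant 1. Of the 589 genes, 72.8% had the same sign between wild type 3 and mutant 3, and of the 204, 27.9%. The 589 were called with these arrays included, so only the share for the 204 is independent of them. With the replicate number as a block, limma called 0 genes (572 at an unadjusted p under 0.05). Samples with the same number deviated in opposite directions (correlations −0.408, −0.423 and −0.519). Samples of unlike genotype and number ran from −0.472 to 0.533. Deviations within a group balance out, so the outlying arrays numbered 3 act on all of these values. They cannot show whether a number marks a shared culture or day.

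The hlh-30 difference passed the threshold at −1.55 with array quality weights (limma adjusted p 0.00649) and at −1.47 without both arrays numbered 3 (0.042). Both settings give little or no weight to those arrays. Over all settings the limma adjusted p of hlh-30 ran from 0.00649 to 0.577. Of the lists, 17 were called in camera, 9 with plain probe sets only, 0 with an estimated correlation and 1 with fry. The mode with an estimated correlation also rests on few residual degrees of freedom, so its lost calls do not measure correlation between genes alone. Without both arrays numbered 3, 11 of the 17 were lost and 6 others gained. Early embryo transcripts changed direction with array quality weights (−0.16), without mutant 3 (−0.15, in a range of −0.15 to 0.26 with any 1 array left out) and without both arrays (−0.22). Their median of −0.051 with the covariate was largely fixed in advance, as the covariate is the mean of that same list. Nuclear hormone receptors turned upward in camera with array quality weights (median −0.0059) and without both arrays (−0.0031), and histones turned downward without both (−0.037). The cause was not tested, except that fewer arrays or probe sets were used where some were left out. Signal over background limits dim genes: 12060 of 22548 probe sets passed the filter.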

Other observations

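The families of genes with a shared symbol prefix were tested as an exploration, 93 in all. With the preset correlation 9 were called. With an estimated one, where the test also rests on few residual degrees of freedom, 0 were called (lowest camera adjusted p 0.859). Of the 9, 5 were higher (rps, rpl, col, his and dbd) and 4 lower (prx, atg, nhr and alh). The peroxin family prx, which builds peroxisomes, where fatty acids are also oxidised, was below 0 in 11 of 11 genes, with a median of −0.32 (camera adjusted p 0.00119). Without wild type 3 and mutant 3 its median was −0.24 and it was not called (camera adjusted p 0.116). The atg family had a median of −0.32 over 12 genes (camera adjusted p 0.00135) and −0.44 without both arrays (0.0125). The aldehyde dehydrogenase family alh had a median of −0.23 over 11 genes (camera adjusted p 0.0411), and −0.13 without both arrays (0.089).

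Probe set 175278_at, which is annotated with no gene, read 6.62 ± 0.072 (SD, n = 3) in wild type and 3.96 ± 0.25 (SD, n = 3) in the mutant, at least 5.82-fold lower with mutant values under 4 set to that minimum (limma adjusted p 0.0210). adh-1, an alcohol dehydrogenase chosen after its values were seen, went from 12.80 ± 0.36 (SD, n = 3) to 10.17 ± 0.49 (SD, n = 3), lower on all 3 mutant arrays, and did not pass the threshold (limma adjusted p 0.0815).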
